A study of Caenorhabditis elegans with 2 samples.

How the data were processed

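Binding of MAB-5 tagged with enhanced green fluorescent protein (eGFP) was measured by chromatin immunoprecipitation followed by sequencing in whole Caenorhabditis elegans larvae of the second larval stage. Per the labels, the animals were of mixed sex and came from strain OP27, which carries an integrated insertion targeting mab-5 and the mutation unc-119(ed3), and the antibody is listed under the name mab-5. The 2 samples are biological replicates of 1 group. No second group and no control sample was analysed here, so no comparison between conditions was possible, and every comparison is between replicates, between genomic regions or between gene lists.

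The authors deposited peak lists, not reads. Per the text record deposited with each sample, each replicate has a relaxed list of peaks and background made against a control alignment. Both replicates' pooled alignments have another. Per the same record, an optimal list was derived from these by the irreproducible discovery rate (IDR), a method based on how reproducibly peaks rank in replicates. The relaxed lists hold 30000 peaks each. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each list was deposited on 2 genome builds, ce11 and ce10. All gene and sequence results use ce11, and ce10 served only for counts and shares that need no annotation. Coordinates were never moved between builds, and all peaks fell within the ce11 chromosome lengths.

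Each peak carries the authors' signal value, a score whose scale is not given in the sources used here, and the deposited −log10 of its q-value. The p-value column is not filled. The −log10 q-value has a ceiling, 3.66 in the pooled list, which all 2197 IDR peaks on ce11 shared, so peaks were ranked by the authors' signal score within a list. It was used only to describe, rank and filter peaks. All 2197 IDR peaks were found unchanged in the pooled list, and they were exactly the 2197 pooled peaks of highest signal. An IDR peak's signal is therefore 1 pooled value with no replicate error. Its rank in each replicate's own list of 30000 is given instead for some of the peaks named. Membership in the IDR list does not show that a peak is strong in both replicates. Of the 2197 IDR peaks, 1408 ranked within the first 2197 of both replicates' lists. No match was found for 19 in replicate 1 and for 7 in replicate 2. Results based on genes or motifs were repeated on the 2197 strongest peaks of each replicate alone. The sequencing depth is unknown, since the lists hold no read counts. Confidence intervals on shares of peaks or genes are 95% Wilson intervals and cover counting error only. The replicates' relaxed lists shared 80 peaks with the same position on ce11, where both had a median width of 336 bp, and 0 on ce10, and they shared no peak with the same position and signal on either build, so they were treated as separate libraries.

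Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes came from Ensembl release 115 for assembly WBcel235, which is ce11, and sequence from the NCBI copy of that assembly. Mitochondrial protein-coding genes that Ensembl leaves unnamed took the RefSeq symbol with the largest overlap. A promoter was the window from 2000 bp upstream to 500 bp downstream of the start of 1 of 19973 nuclear protein-coding genes, and a gene with a summit in this window is called bound here. The word says nothing of regulation, nor of whether MAB-5 itself or chromatin recovered without it gives the peak. The 23 IDR peaks on the mitochondrial genome were left out of gene, motif, location and tRNA analyses.

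The main choices were made before the data were examined. Peaks were matched between lists by an overlap of at least 1 bp. Overlap expected by chance came from 100 circular shifts, each moving all peaks of a chromosome by the same random distance, and a two-sided p from 100 shifts cannot fall below 0.0198. The rank correlation used 100000 permutations across peaks, which are not independent replicates. Chromosome shares were tested with exact binomial tests against chromosome length, and autosome centres were the inner 40% of each chromosome. Gene lists numbered 21, of which 13 named genes and 8 took gene-name prefixes. Each was tested with Fisher's exact test, two-sided, against all other protein-coding genes. Of the names in the lists, 10 had no protein-coding match, 5 of them microRNA genes, which are only described. Neighbouring genes can share a peak, so genes are not fully independent in these tests. Motif shares within 100 bp of summits were compared with windows 1000 bp to a randomly chosen side by exact McNemar tests, and those against GC-matched promoter windows by Fisher's exact test, where 120 peaks had no match. Random lists matched on upstream distance numbered 10000. P-values were adjusted by the Benjamini-Hochberg method within chromosomes, lists and motifs.

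The genes named were fixed by rule before the data were examined. They are the genes nearest to the 10 IDR peaks of highest signal, all Hox and Hox cofactor genes, up to 4 bound members of every other list in order of signal, and mab-5 and unc-119. Because the 10 strongest peaks proved to be mitochondrial, genes near the strongest nuclear peaks were named as well, after their values were seen. Alternatives covered the overlap rule, the size of the lists, the other genome build, leaving out each replicate, the 1098 strongest IDR peaks, promoter windows from 1000 bp upstream to 200 bp downstream and from 5000 bp upstream to 500 bp downstream, any transcript start, assignment of each peak to the nearest gene start, random lists matched on the distance to the next gene upstream, and other motif windows and controls. A set without peaks at ribosomal protein promoters, the composite motif read backwards, the motif GCGCAGGG, gene-name prefixes and gene biotypes were added after seeing the data.

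The tests were tested on simulated data with random peaks. With peaks placed at 35% of the members of 3 lists, among 19973 genes, the list test called the planted lists in all 60 trials and called 2 of 360 unplanted ones. With a composite motif placed in 10% of 2174 windows, the motif test called it in all 20 simulations, and it called 2 of 100 other motifs. The planted share is above the real difference for the composite, 5.70 percentage points. Simulated peaks lay at random over the genome, so they were not concentrated at promoters. Their windows had no built-in GC difference from controls, whereas real ones averaged 43.6% and 36.4%. The rates of false calls therefore do not carry over to the real lists.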

Results

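The data describe where chromatin was recovered by immunoprecipitation against eGFP-tagged MAB-5 in whole second-stage larvae. MAB-5 is the Antennapedia-class Hox protein that patterns the posterior body and the left Q neuroblast lineage. Whether MAB-5 itself gives a peak was not tested. The 2 biological replicates gave 2197 peaks that passed the IDR procedure on ce11, and 2217 on ce10. The peaks had a median width of 344 bp and covered 0.674% of the nuclear genome. Of the 2197 peaks, 2174 lay on nuclear chromosomes and 23 on the mitochondrial genome. The read depth behind the lists is unknown.

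The strongest peaks of all were mitochondrial. The IDR peaks ranked 1 to 18 by signal lay on the 13794 bp mitochondrial genome, as did the 20 strongest peaks of replicate 1 and 19 of the 20 strongest of replicate 2. The 10 strongest lay nearest to the starts of ND5, CYTB, ND4, COX3, ND1, ATP6 and ND3, all components of the respiratory chain or ATP synthase, and of 3 mitochondrial tRNA genes (WBGene00014466, WBGene00014471 and WBGene00014455). The strongest, at positions 12287 to 12593 near ND5 (signal 2543), ranked 1 in both replicates. For comparison, the strongest nuclear peak had a signal of 361.

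The 20 strongest nuclear peaks included 10 on X, 2 of them in introns and the others between protein-coding genes, and peaks upstream of ribosomal protein genes and of mab-5 itself. The strongest of all, on X at 11094021 to 11094395 (ranks 21 and 23 in replicates 1 and 2), lay 3989 bp from the start of W02H3.3, its nearest protein-coding gene. Within 100 bp of its summit it held a Hox-PBC composite, the sequence bound jointly by Hox and PBC homeodomain proteins, and GCGCAGGG, part of the motif of sites that recruit the dosage compensation complex to X. GCGCAGGG was held by 10 of the 20 X peaks and 0 of the 80 autosomal ones among the 100 strongest nuclear peaks (a motif added after the data were seen). The next strongest, on chromosome III at 3867447 to 3867706 (signal 336, ranks 24 and 21), lay 288 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Others among the 20 strongest lay upstream of rpl-35 (signal 236), rpl-15 (signal 216), tasp-1 (signal 300.6), cdc-48.1 (signal 273) and cox-5A (signal 229.5). The peak on X at 14525741 to 14526118 lay 736 bp from the start of nspc-17 (signal 314).

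The replicates gave overlapping sets of peaks. Replicate 1's relaxed list held 2178 of the 2197 IDR peaks (99.1%, interval 98.7 to 99.4), and that of replicate 2 held 2190 (99.7%, interval 99.3 to 99.8), against 19.1% and 18.9% on average after circular shifts. Of the 2197 strongest peaks of replicate 1, 1438 overlapped 1 of the 2197 strongest of replicate 2 (65.5%, interval 63.4 to 67.4), against 2.23% on average in 100 shifts and at most 2.64%. Signal ranks over the 2172 IDR peaks matched in both lists correlated with a Spearman's rho of 0.475 (permutation p = 1e-05, the smallest that 100000 permutations can give). This correlation is across peaks, which are not independent replicates. Overlap alone is a weak criterion, because the IDR list was built from these replicates. The shares fell to 86.8% and 90.03% when each peak had to cover 50% of the other.

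**Figure D1:**
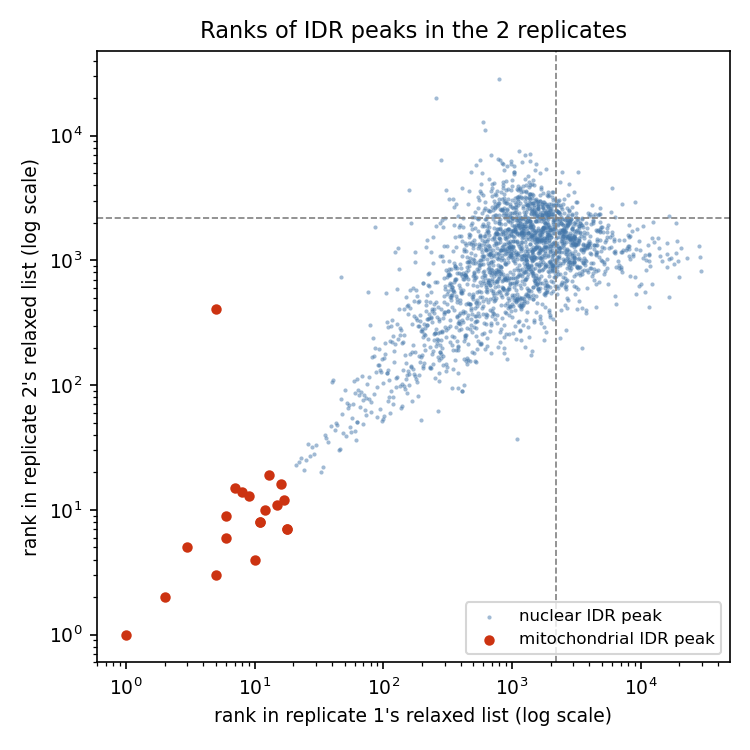
Rank of each IDR peak in the relaxed list of replicate 1 (x axis, log scale) and of replicate 2 (y axis, log scale), for the 2172 IDR peaks matched in both. Red points are mitochondrial peaks, blue points nuclear peaks, and dashed lines mark rank 2197; the strongest peaks are mitochondrial in both replicates, and 1408 IDR peaks rank within the first 2197 of both lists.

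Nuclear peaks lay mostly between genes and close to gene starts. Summits fell between protein-coding genes in 69.96% (interval 68 to 71.9), against 36.8% on average after shifts, and in coding exons in only 1.20% (interval 0.817 to 1.75), against 24.4%. Introns held 24.8%, below the 33.8% average of the shifts. Promoter windows held 59.9% of summits (1302 of 2174, interval 57.8 to 61.9), which was 1.53 times the 39.1% average of 100 shifts (permutation p = 0.0198, two-sided, the smallest these shifts can give). The 2197 strongest peaks of replicate 1 and replicate 2 alone gave 58.4% and 58.9%. Summits within 500 bp of 1 of 612 nuclear tRNA gene starts numbered 58 (2.67%, interval 2.07 to 3.43), 4.63 times the average of the shifts (permutation p = 0.0198, again the smallest possible). The ratio was 10.06 within 200 bp and 3.07 with the 1098 strongest peaks.

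Peaks were denser on chromosome III, denser in the centres of autosomes and sparser on chromosome V. Chromosome III carried 17.2% of nuclear peaks with 13.7% of the nuclear genome (exact binomial test, adjusted exact p = 2.14e-05), and chromosome V carried 14.7% with 20.9% (adjusted exact p = 1.39e-12). The centres of the autosomes, 40% of their length, held 900 of 1742 autosomal peaks (51.7%, interval 49.3 to 54.01, exact p = 8.73e-23). These held with each replicate alone. Chromosomes I (17.6% against 15.03%, adjusted exact p = 0.00237), X (19.9% against 17.7%, adjusted exact p = 0.0123) and IV (15.4% against 17.4%, adjusted exact p = 0.0143) also departed from their length. Over the alternatives, adjusted p ran from 0.00159 to 0.201 for chromosome I, which missed the threshold without replicate 1, from 0.000164 to 0.108 for X and from 0.0109 to 0.177 for IV, which missed it without replicate 2. Chromosome II held 15.3% with 15.2% of the length (adjusted exact p = 0.952).

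Of the Hox genes, mab-5, lin-39 and ceh-13 were among the most densely bound loci, while egl-5, nob-1 and php-3 had 0, 0 and 1 peaks within 20 kb. Within 50 kb, a window that reaches the peaks around mab-5, egl-5 had 13. Within 20 kb of the start of mab-5 lay 12 IDR peaks, more than around 99.985% of protein-coding genes, for which the median was 1, and replicates 1 and 2 alone gave 13 and 11. The neighbouring Hox genes lin-39, needed for vulval precursor cells and the mid-body, and ceh-13, the labial-class Hox gene, had 11 and 8 such peaks, more than 99.97% and 99.9% of genes; their windows share peaks, and hold 14 between them. The gene unc-119, whose mutation the strain carries, had 2. Of the 6 Hox genes, mab-5, ceh-13 and lin-39 had a promoter peak, and the posterior genes egl-5, nob-1 and php-3 had none (50% bound against 9.58% of other genes, odds ratio 9.44, Fisher's exact test, adjusted exact p = 0.0269, in both replicates alone as well). Adjusted p over the alternatives ran from 0.0187 to 0.0917, past the threshold in 6 of 8. With 6 genes the interval of the share, 18.8% to 81.2%, is wide. The list also includes mab-5 itself, which the integrated transgene carries, so its peak could come from extra copies. The list was not tested without mab-5.

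The mab-5 gene (WBGene00003102) spans 7776835 to 7783454 on the minus strand of chromosome III. Its strongest peak, at 7784160 to 7784626, had its summit in intergenic sequence 957 bp upstream of the gene start (signal 246, ranks 46 and 31). The peak with the next highest signal lay in an intron, at 7780487 to 7780874 (signal 144, ranks 108 and 75). Around ceh-13 (WBGene00000437, 7555660 to 7558041, plus strand) the strongest peak, at 7554733 to 7555011, lay 773 bp upstream (signal 182, ranks 57 and 55) and held a Hox-PBC composite site, TGATTTAT, at 7554868 to 7554875. For lin-39 (WBGene00003024, 7528641 to 7536632, minus strand) the promoter peak, 54 bp upstream, was weak (signal 38.9, ranks 797 and 2319), and the strongest peak in the gene body lay in an intron at 7534735 to 7534905 (signal 130, ranks 141 and 102). Of the peaks within 20 kb, 5 of 12 around mab-5, 3 of 11 around lin-39 and 3 of 8 around ceh-13 held a composite within 100 bp of the summit. Over all nuclear summits the share was 16.7%. The peaks with a composite at 7548985 to 7549328 and 7554733 to 7555011 count for both lin-39 and ceh-13. The strongest peak of mab-5 held none.

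**Figure D2:**
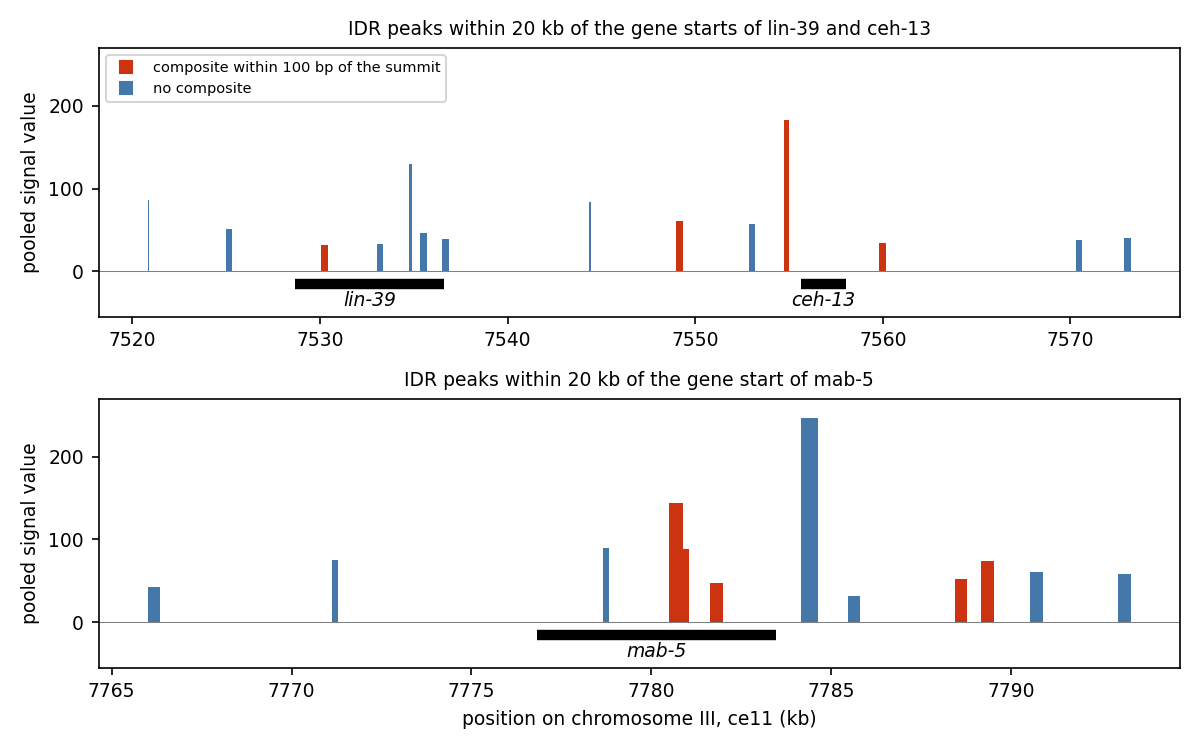
IDR peaks within 20 kb of the gene starts of lin-39 and ceh-13 (top) and of mab-5 (bottom), by position on chromosome III of ce11 in kb (x axis) and pooled signal value (y axis). Bars are as wide as the peaks, red bars hold a composite within 100 bp of the summit, black bars are genes, and the tallest bars are the peaks upstream of mab-5 (signal 246) and ceh-13 (signal 182).

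Of the 5 Hox cofactor genes, ceh-20, which encodes a PBC-class partner of Hox proteins, had a promoter peak 799 bp upstream (signal 61.1, ranks 401 and 781), and ceh-40, ceh-60, unc-62 and psa-3 had none (adjusted exact p = 0.489). The MEIS-class gene unc-62 nevertheless had 6 peaks within 20 kb of its start.

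In all, 1916 of 19973 protein-coding genes (9.59%) had an IDR summit in the promoter window, and 1844 and 1872 did with the strongest peaks of replicate 1 and replicate 2 alone. Of the 21 gene lists, 6 were bound more often than other genes and 5 less often at an adjusted p below 0.05.

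Ribosomal protein genes stood highest in the promoter window: 55 of 81 were bound (67.9%, interval 57.1 to 77.1, odds ratio 20.5, adjusted exact p = 9.75e-36), through 53 peaks. The strongest were at rpl-3, rpl-20 (signal 268), rpl-35 and rpl-15. Replicates 1 and 2 alone gave 67.9% and 63.0%. The list was past the threshold under all 7 alternatives, with 38.3% and an odds ratio of 6.04 when each peak went to the nearest gene start. Under that rule it no longer stood highest. Heterochronic genes reached 61.5% (odds ratio 15.4), Hox genes 50%, migration and axon guidance genes 48.6%, and motor and touch neuron genes 45%. Wnt and Hox cofactor genes each reached 40%.

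Genes of the Wnt pathway, which controls mab-5 expression in the left Q neuroblast, were bound at 9 of 30 members (30%, odds ratio 4.05, adjusted exact p = 0.00392). The 4 strongest were the Dishevelled gene mig-5 (180 bp upstream, signal 180, ranks 54 and 69), the Frizzled receptor gene lin-17 (542 bp upstream, signal 99.1, ranks 136 and 285), the Axin-like gene pry-1 (signal 48.9) and the planar polarity gene vang-1 (signal 47.6). Adjusted p stayed below 0.05 under all 8 alternatives, at 2.46e-05 to 0.0478, and the nearest gene start gave 12 of 30 (odds ratio 6.44).

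Among genes of motor and touch neurons, 11 of 40 were bound (27.5%, odds ratio 3.59, adjusted exact p = 0.00309). These included the proprotein convertase gene egl-3 (signal 62.6), unc-25, which encodes the GABA-synthesizing enzyme (177 bp upstream, signal 59.9, ranks 888 and 714), the neuronal gene rgef-1 (signal 49.2) and the syntaxin gene unc-64 (signal 48.5). This list lost its call with the 1098 strongest peaks and with the 5000 bp window. Adjusted p over the alternatives ran from 2.02e-08 to 0.289. No gene named mec was bound in the promoter window (0 of 16). The mec genes of touch neurons in this list are among these, so the list's call came from its other members.

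Heat shock and stress genes were bound at 8 of 31 (25.8%, odds ratio 3.29, adjusted exact p = 0.0174), led by the mitochondrial chaperonin gene hsp-60 (622 bp upstream, signal 202, ranks 39 and 47), the hypoxia factor gene hif-1 (signal 118.7) and the chaperone genes hsp-3 (signal 117) and hsp-1 (signal 92.5). Adjusted p over the alternatives ran from 0.00036 to 0.258, above 0.05 with the 5000 bp window and with the nearest gene start. Replicate 1 alone gave 7 of 31 (odds ratio 2.87) and replicate 2 alone 11 of 31 (odds ratio 5.34). Histone genes were bound at 14 of 72 (19.4%, odds ratio 2.28, adjusted exact p = 0.0179), through 10 peaks, several shared by neighbours such as his-35 and his-37 (signal 116) and his-67 and his-68 (signal 73.4). Against random lists matched on the distance to the next gene upstream the histone call ended (adjusted permutation p = 0.393, range over the alternatives 0.00217 to 0.883). It also ended with the 5000 bp window (odds ratio 1.61, adjusted exact p = 0.159) and with the nearest gene start (7 of 72, odds ratio 1.03, adjusted exact p = 0.883).

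In all, 5 lists of large gene families were bound less often than other genes. Of 1029 chemoreceptor genes 11 were bound (1.07%, odds ratio 0.0966, adjusted exact p = 1.25e-30), the strongest being srh-16, sri-5, srh-17 and srd-43. Of 322 F-box genes 5 were bound (1.55%, odds ratio 0.146, adjusted exact p = 3.5e-08), among them fbxb-58, fbxa-90, fbxb-85 and fbxa-141. Neuropeptide genes were bound at 2 of 140, ins-39 and nlp-76 (1.43%, adjusted exact p = 0.000751), collagen genes at 4 of 156, col-94, col-71, col-38 and col-2 (2.56%, adjusted exact p = 0.00309), and nuclear hormone receptor genes at 10 of 269, led by nhr-47, nhr-142, nhr-1 and nhr-48 (3.72%, adjusted exact p = 0.00149). Neuropeptides (adjusted p over the alternatives 0.000258 to 0.206) and receptors (0.000141 to 0.138) missed the threshold when each peak went to the nearest gene start.

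The remaining lists missed the threshold in the promoter window with the IDR peaks. Neuroblast migration and axon guidance genes were bound at 6 of 37 (16.22%, adjusted exact p = 0.228), among them mig-13, a transmembrane protein gene that acts in Q neuroblast migration (286 bp upstream, signal 100.5, ranks 279 and 164), the netrin receptor gene unc-40 (signal 49.99), the plexin gene plx-1 (signal 49.8) and mig-17 (signal 32.7). When each peak was given to the nearest gene start at any distance, 18 of the 37 had one (48.6%, odds ratio 9.17, adjusted exact p = 5.68e-09, range over the alternatives up to 1), unc-5, unc-6 and vab-1 among them (chosen after their values were seen). The nearest-start rule has no distance limit, so genes with more sequence around their starts can receive more peaks. It was not run against lists matched on upstream distance, for this or any other gene list. Heterochronic genes, which time larval stages, were bound at 4 of 13, lin-14 (signal 64.1), ain-1 (signal 62.1), lin-41 (signal 51.1) and alg-2 (signal 38.9), with an adjusted p of 0.0521. Their adjusted p over the alternatives ran from 1.8e-05 to 0.383, past the threshold in 3 of 8. With the nearest gene start 8 of 13 had a peak, hbl-1, lin-28, lin-42 and daf-12 in addition (chosen after their values were seen). Replicate 2 alone gave an adjusted exact p of 0.0446, and leaving out peaks at ribosomal protein promoters 0.0423. Replicate 1 alone gave 3 of 13 (adjusted exact p = 0.18), and the 1000 bp window 2 of 13 (adjusted exact p = 0.383). Of the heterochronic microRNA genes, let-7 had a peak 1822 bp upstream (signal 54.5), and lin-4, mir-48, mir-84 and mir-241 had none in the window.

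Seam, ray and epidermal genes were bound at 3 of 35 (mab-5, tlp-1 and lin-14, adjusted exact p = 1); with the nearest gene start the figure was 8 of 35 (odds ratio 2.85, adjusted exact p = 0.0302, range over the alternatives up to 1). Vulval genes were bound at 5 of 33, among them lin-10, lin-39, lin-7 and the Ras gene let-60 (adjusted exact p = 0.317). The let-60 peak had no match in the relaxed list of replicate 1 and ranked 1015 in replicate 2. M lineage genes were bound at 1 of 25, dbl-1 (odds ratio 0.392, adjusted exact p = 0.575; 2 of 25 and an odds ratio of 0.841 with replicate 2 alone), and homeobox genes named ceh at 4 of 63, ceh-13, ceh-38, ceh-20 and ceh-5 (adjusted exact p = 0.575). Body wall muscle genes were bound at 7 of 38, led by unc-97, unc-60, act-2 and act-4 (adjusted exact p = 0.133), and had an adjusted p of 0.0393 with replicate 2 alone and 0.0263 with the 5000 bp window (range over the alternatives 0.0263 to 0.761). Germline genes were bound at 3 of 41, nos-3, cgh-1 and pie-1 (adjusted exact p = 0.834). No intestine marker of 33 was bound (upper limit of the interval 10.4%, adjusted exact p = 0.113).

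**Figure D3:**
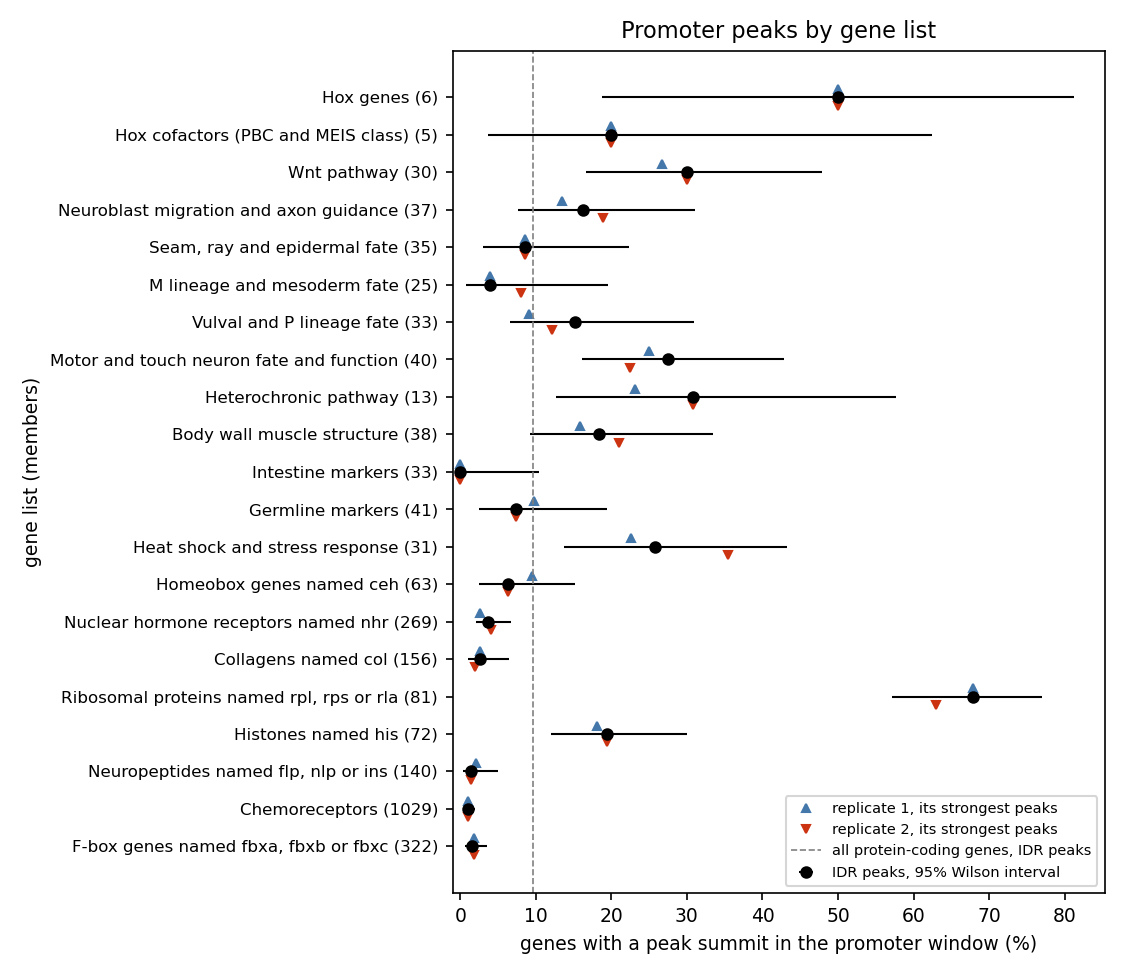
Percentage of each gene list's members with a peak summit in the promoter window (x axis) for the 21 lists (y axis, number of members in parentheses). Black points with 95% Wilson intervals are IDR peaks, triangles are the 2197 strongest peaks of replicate 1 or 2 alone, and the dashed line is the 9.59% of all protein-coding genes; ribosomal proteins stand highest at 67.9%.

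Motifs near the summits separated the composite from the simple Hox core. The Hox-PBC composite TGATWNAT lay within 100 bp of 363 of 2174 summits (16.7%, interval 15.2 to 18.3) and in 10.99% of control windows 1000 bp away (exact McNemar test, adjusted exact p = 4.85e-08). Replicate 2 alone gave a difference of 6.02 percentage points and replicate 1 alone 2.21. With the 1098 strongest peaks the difference was 2.60 points and no longer past the threshold (adjusted p over the alternatives 7.22e-17 to 0.1). The core TAATKR was less frequent in peaks, at 24.3% against 34.5% (adjusted exact p = 3.85e-13), and so was its reversed sequence, a negative control, at 20.2% against 30.8% (adjusted exact p = 4.39e-15). The repeat GAGAGAGA showed the widest ratio of the 6 planned motifs, in 274 of 2174 peaks against 2.02% of controls (adjusted exact p = 4.17e-44). GATA sites were less frequent, at 31.0% against 36.6% (adjusted exact p = 0.000104), and E-boxes more frequent, at 15.5% against 12.5% (adjusted exact p = 0.00534). Peak windows averaged 43.6% GC and control windows 36.4%. Against promoter windows of like GC content without a peak, the composite stayed higher in peaks by 8.91 points and the GA repeat by 7.40. The difference of the Hox core shrank from −10.2 to −3.94 points (adjusted exact p = 0.00988) and that of GATA sites from −5.66 to −3.21 (adjusted exact p = 0.0468), the E-box difference turned to −1.56 points (adjusted p over the alternatives 5.87e-05 to 0.199), and the reversed core differed by −1.70 points, no longer past the threshold (1.66e-17 to 0.199).

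**Figure D4:**
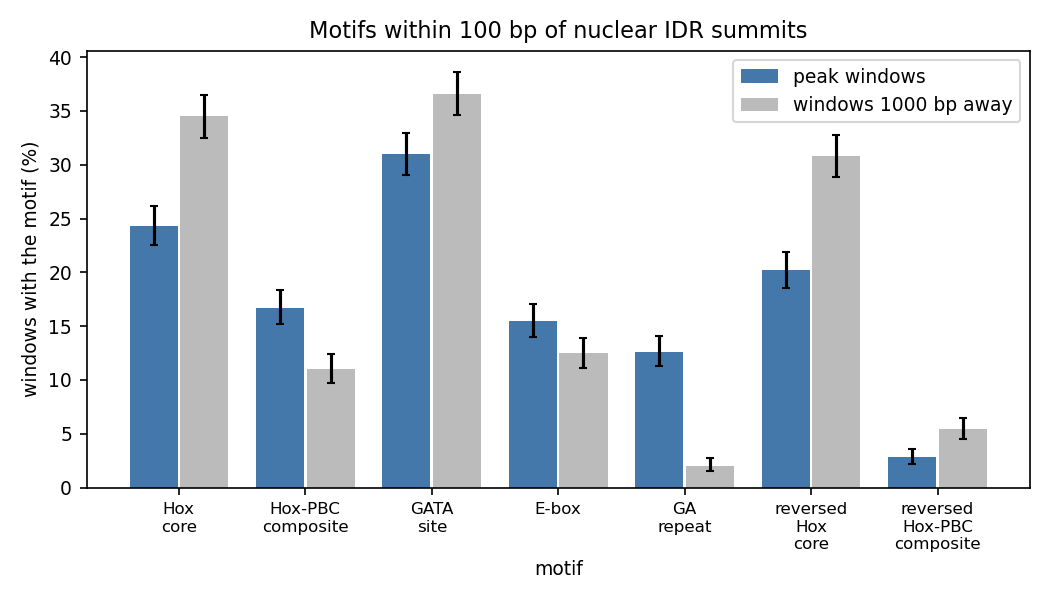
Percentage of windows holding each motif (y axis) for 7 motifs (x axis), in windows within 100 bp of nuclear IDR summits (blue) and in windows 1000 bp away (grey). Error bars are 95% Wilson intervals; the composite (16.7% against 10.99%) and the GA repeat (274 peaks against 2.02% of windows) are higher in peaks and the Hox core (24.3% against 34.5%) is lower.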

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

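The test of mitochondrial coverage was chosen after that result was seen, and the test of the composite before. The 23 IDR peaks on the mitochondrial genome belong to no comparison of genes or motifs and were singled out because they lie outside the nuclear genome, where a transcription factor is measured. They covered 39.5% of the mitochondrial genome, 58.7 times the share of the nuclear genome that IDR peaks covered. Such spread is consistent with the many copies of this genome in each cell as a candidate explanation. The lists were made against a control alignment, and how far it offset these copies was not tested. Whether binding at the composite contributes cannot be told apart, since 8.70% of the 23 mitochondrial summits held one (interval 2.42 to 26.8) against 11.2% on average in 1000 circular shifts, and the interval reaches above the 17.04% that the nuclear enrichment would give. No explanation by a difference between groups was tested, as the series has 1 group.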

How the results depend on the processing

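The call for chromosomes III and V, the autosome centres, promoters, tRNA genes, the Hox core, GATA sites and the GA repeat kept its direction and side of the threshold under every alternative run for it, as did Wnt, collagen, ribosomal protein, chemoreceptor and F-box genes. Read depth is unknown and its limit was not tested. Where values moved, the cause was not tested, except that fewer peaks or a wider window change a count by construction. The 1098 strongest IDR peaks, 50% of the list, gave 1071 bound genes, presence in replicate 1 of 99.8%, 19.8% of peaks on X and 15.7% on IV (both no longer past the threshold), 14.2% on II, differences of 2.60 points for the composite and 2.14 for E-boxes (neither past the threshold), and a 91.3 percentile for unc-119. The 5000 bp window gave 3013 genes and 3 lists above other genes, and the nearest gene start gave 3 lists below. Presence in replicates 1 and 2 was 86.8% and 90.03% with 50% reciprocal overlap and 95.8% and 97.8% with summits within 100 bp, and 98.3% in replicate 1 with the stronger 50% of its relaxed list. The replicates' overlap of strongest peaks was 58.4% and 59.5% under the same rules and 61.3% with 2 times as many peaks. The percentile of mab-5 was 99.8 within 50 kb, that of egl-5 rose from 0 within 20 kb to 99.8 within 50 kb, and that of unc-119 was 91.6 within 10 kb and 62.5 within 50 kb. GC-matched promoters turned E-boxes to −1.56 points, left the reversed core at −1.70, and brought the Hox core from −10.2 to −3.94 and GATA sites from −5.66 to −3.21, both still past the threshold. Leaving out each replicate in turn gave 16.09% to 17.6% for chromosome I, 15.08% to 15.10% for II, 15.3% to 15.8% for IV, a percentile of 51.1 to 78.5 for unc-119, and odds ratios of 0.983 to 1.33 for vulval, 0.763 to 1.063 for germline, 0.655 to 1.03 for ceh genes, 0.409 to 0.841 for M lineage genes and 0.139 to 0.214 for neuropeptide genes. Among lists not past the threshold in the main analysis, odds ratios crossed 1 for migration genes (0.742), vulval (0.838), germline (1.03) and seam genes (1.22) with the 1000 bp window, for seam genes with the 5000 bp window (1.16), the matched background (1.14) and the nearest gene start (2.85, there past the threshold), for M lineage genes with the nearest gene start (1.31), and with the 1098 strongest peaks for seam (1.66), muscle (0.477) and vulval genes (0, none bound). Of the list results under alternatives, 136 kept direction and side of the threshold, 6 passed it newly in the same direction, 11 no longer passed it and 14 crossed an odds ratio of 1, of which 1 (seam genes with the nearest gene start) also passed the threshold newly. On ce10 the IDR list held 2217 peaks against 2197, and the overlaps, correlation and chromosome shares run there moved by less than their intervals.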

Other observations

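All tests here were chosen after the data were seen, except the test of IDR shares around mab-5. Over 175 gene-name prefixes with at least 10 members, 20 were bound more often than other genes and 12 less often (Fisher's exact test, Benjamini-Hochberg adjusted). Among the 20 above were mitochondrial ribosomal proteins (mrpl, 13 of 41, adjusted exact p = 0.00132), vacuolar ATPase subunits (vha, 8 of 20, adjusted exact p = 0.00413), Rab GTPases (rab, 8 of 20, adjusted exact p = 0.00413), translation initiation factors (eif, 9 of 25, adjusted exact p = 0.00413), nuclear pore proteins (npp, 9 of 26, adjusted exact p = 0.00508) and proteasome regulatory subunits (rpn, 6 of 13, adjusted exact p = 0.00712). Others with core functions missed the threshold, such as mrps (6 of 29, adjusted exact p = 0.162), taf (5 of 17, adjusted exact p = 0.0863), rpb (3 of 11, adjusted exact p = 0.212) and gtf (0 of 10, adjusted exact p = 0.738). Prefixes from mutant phenotypes were mixed: 34 of 94 unc genes (adjusted exact p = 1.51e-10) and 19 of 47 lin genes (adjusted exact p = 7.28e-07) were bound, above other genes, and so were 6 of 16 mig genes (adjusted exact p = 0.0172), while let (8 of 34, adjusted exact p = 0.0654), egl (3 of 27, adjusted exact p = 0.83), daf (1 of 26, adjusted exact p = 0.706), dpy (2 of 25, adjusted exact p = 1) and mec (0 of 16, adjusted exact p = 0.592) missed the threshold. Among the 12 below were C-type lectins (clec, 4 of 240, adjusted exact p = 3.64e-05) and cytochrome P450 genes (cyp, 0 of 74, adjusted exact p = 0.00906).

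Small nucleolar RNA genes were bound at 110 of 346 (31.8%, interval 27.1 to 36.9, odds ratio against protein-coding genes 4.39, adjusted exact p = 4.62e-29). Pseudogenes were bound at 31 of 2128 (1.46%, adjusted exact p = 2.23e-50) and microRNA genes at 26 of 261 (9.96%, adjusted exact p = 0.832). A window can hold the peak of a neighbouring gene: the peak of the microRNA gene mir-354 was also that of rps-20. The shares for these gene types were not tested without such peaks. Peaks at ribosomal protein promoters held the composite in 1 of 53 cases and the GA repeat in 0 of 53, against 17.1% and 12.9% of other peaks (Fisher's exact tests, p = 0.00117 and 0.00122). Whether MAB-5 itself or chromatin recovered without it gives the peaks at ribosomal protein promoters was not tested either way, as no control immunoprecipitation was analysed here. The composite was in 15.3% of the 544 strongest nuclear peaks and 18.97% of the 543 weakest (Fisher's exact test, p = 0.108). Its reversed sequence, an added control, was in 2.81% of peaks against 5.43% of control windows (adjusted exact p = 1.08e-05).

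Peaks clustered around mab-5, which the transgene carries. Of the pooled relaxed peaks within 20 kb of mab-5, 28.6% passed IDR (12 of 42), against 26.9% (14 of 52) around lin-39 and ceh-13, a difference of 1.65 percentage points (Fisher's exact test, p = 1). Extra copies on the transgene and binding at the native gene cannot be told apart from this, because the peaks are few and the copies share 1 sequence. Both lin-39 and ceh-13 were at or above the 99.9 percentile of genes for nearby peaks, which is consistent with dense binding at these Hox genes as a hypothesis. The posterior genes egl-5, nob-1 and php-3 had 0, 0 and 1 IDR peaks within 20 kb.

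An excess of X among the 100 strongest nuclear peaks was looked for first and not found: 20 were on X, against 19.9% of other peaks (Fisher's exact test, p = 1). Of the 20 strongest, however, 10 were on X, which has 17.7% of the nuclear length (exact binomial test, p = 0.000966). Of the 500 strongest, 94 were (exact binomial test, p = 0.519). The pattern taken up in place of this excess concerned GCGCAGGG, part of the motif of sites that recruit the dosage compensation complex to X. The motif lay within 100 bp of 20 nuclear summits, 19 of them on X, and in 0 control windows. A higher number of copies on X did not account for this, since 23 of 81 copies on X (28.4%) had a summit within 100 bp, against 1 of 233 on autosomes (Fisher's exact test, p = 4.07e-14). The motif was taken up after being seen in X peaks and not in autosomal ones, so a higher share on X was partly built in. Copies that share a summit are also not independent. The longer match TCGCGCAGGG had a summit at 13 of 19 copies on X and 0 of 6 on autosomes (Fisher's exact test, p = 0.00522). This argues only weakly against the longer match as the cause. It rests on 6 autosomal copies, of which at most the 1 counted above could have had a summit. Other and longer matches were not tested and stay open. Whether MAB-5 itself or chromatin recovered without it gives these peaks stays open and was not tested, as a control immunoprecipitation and other factors were not analysed here.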
